A study of Mus musculus with 2 samples.

How the data were processed

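Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody against green fluorescent protein (GFP) on snap-frozen heads of mouse embryos at embryonic day 10.5, and libraries were sequenced on a HiSeq instrument, per the labels. The labels gave both libraries the same tissue and the same antibody. They named no contrast, no sex, no litter and no protein that carried GFP. The 2 libraries were therefore treated as 1 group and called library 1 and library 2. Nothing in the labels states that they came from separate embryos, so no p-value here describes a difference between animals or conditions. Each describes positions within these 2 peak lists.

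Each library had its own deposited peak list in the narrowPeak format of the peak caller MACS2. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0, and the genome builds hg38 and mm10, without their roles or settings. The chromosome names and positions of both deposited lists matched mouse build mm10, and all coordinates here are mm10, counted from 1. For each peak the deposited file gives a score, which equalled 10 times the −log10 q cut to a whole number. The deposited lists also give the fold enrichment of the summit over background as a ratio, and the −log10 p-value and −log10 q-value that the authors' caller computed. A summit offset within the peak completes the deposited record. These values are the authors'. As given, they were used to describe, rank or filter peaks within a list, and they were also the source of the pileup and depth estimates that are compared between the libraries.

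MACS2 computes fold enrichment from the summit pileup (the number of overlapping extended reads) and a local background. It computes the p-value from the same pair with a Poisson distribution. Both quantities were solved for jointly from the fold and the −log10 p-value of each peak, with a tolerance of 0.002 on the −log10 scale. A whole pileup was recovered for 100% of the peaks of each library, and the largest mismatch was 0.000152 in library 1 and 6.99e-05 in library 2. The most frequent background in a list was read as the genome-wide background, and the narrowest peak as the extension length. Steps in the local background gave the scaling of the control library. Read numbers derived from these assumed a mappable mouse genome of 1.87e+09 bp, the caller's preset for mouse. On simulated lists of 3000 peaks, 100% of pileups were recovered. Intervals on counts are 95% exact Poisson intervals and intervals on shares are 95% Clopper-Pearson intervals. They cover counting error only.

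Gene positions came from an NCBI RefSeq gene table of the same assembly, GRCm38.p6, restricted to 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table gives the lower and the higher end of a gene without its strand, exons or transcripts. The window planned around transcription starts was therefore replaced by a window of 1 kb around either annotated end, and the classes exon and intron were merged into the gene body. Planned comparisons of GC content and repeats, and of gene lists against genes of the same GC content, were not run, because no genome sequence was used here.

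Overlap of the lists was the share of library 2 peaks sharing at least 1 bp with a library 1 peak. It was compared, one-sided, with 1000 random placements that kept peak width and chromosome. Gene ends and the positions of summits were compared, two-sided, with 100 random placements of all peaks within the span between the first and the last peak of a chromosome. Assembly gaps were not excluded. The smallest two-sided p that 100 placements allow is 0.0198. Peak density was taken over the same spans. The relation of peak and gene density over the 19 autosomes was tested by permutation.

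Gene lists numbering 17 were fixed before the data were examined. They covered eye and lens regulators, crystallin and lens fibre genes, photoreceptor genes, neural patterning regulators, neural crest and craniofacial regulators, Hox genes, signalling genes, ribosomal protein genes, replication-dependent histone genes and genes of chromatin and H3 chaperones. For other cell types and silent genes, the lists held blood, endothelial, hepatocyte, germline, olfactory receptor, vomeronasal receptor and keratin-associated protein genes. Members with a peak at either end were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 17 lists, in library 1. Neighbouring genes are not independent, so 3 additional tests were chosen after seeing the data. These matched genes on length deciles (exact conditional test), kept autosomes only, or moved each list along the gene order by 999 rotations. On simulated data over 21887 genes, Fisher's test called 26% of unchanged lists of 60 neighbouring genes and the rotation test called 2%. Of simulated lists of 60 genes with a peak share of 95%, 100% passed both Fisher's test and the test by length, at unadjusted p under 0.05. Peaks were placed at random there, which gives fewer other genes a peak (62.4% on average) than the data had (78.3%). The 100% therefore does not carry over to smaller lists or to adjusted p-values here.

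Genes are named by a rule fixed before the data were examined. In each library, peaks were walked by descending fold until 10 different protein-coding genes whose body, or 1 kb beyond it, held a peak were named. Of each list, the 2 members with the highest fold at an end in library 1 were named, with any member that held such a peak in library 2. Other members can share the value of a named gene. A gene that the rule names for library 2 is not reported here. Pax6, Six3, Rax, Foxe3, Pitx3, Sox2, Otx2 and the genes for histone H3.2 were always named. Alternatives used peaks with −log10 q of at least 5, fold of at least 5 or the 10% of peaks with the highest fold, a window of 5 kb, stricter overlap, other placements, a single gene end and, chosen after seeing the data, 1 library 2 peak per run of peaks within 10 kb. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.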

Results

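Chromatin recovered with an antibody against GFP was profiled by ChIP-seq in heads of mouse embryos at E10.5, a stage when the optic cup and lens vesicle form. The series addresses functions in the eye of histone H3.2, a core histone made during DNA replication. The data comprised 2 libraries with identical labels, each with its own list of called peaks. The labels do not say whether either library served as a control, such as tissue without GFP. There was no second condition, so the results describe where the peaks of each library lay and how the lists compared. There are no replicate values within a library.

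Library 1 held peaks across every chromosome, whereas library 2 held few, and most of those were on unplaced sequence. Library 1 had 584724 peaks covering 150.6 Mb, and library 2 had 348 peaks covering 37.2 kb, a ratio of 1680. In library 1, 649 peaks (0.111%) lay on unplaced or unlocalised sequence. In library 2 this number was 221 of 348 (63.5%), and 174 peaks (50%) fell on a single unplaced sequence between positions 68565 and 114420. Peaks had a median width of 201 bp in library 1 (range 119 to 8736) and 76.5 bp in library 2 (51 to 573). The median fold enrichment given by the authors was 3.90 in library 1 and 4.27 in library 2, and the highest values were 16.1 and 35.2.

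The reads behind the peaks also differed. Pileups count reads extended to 119 bp in library 1 and 51 bp in library 2. The median summit pileup was 15 reads in library 1 and 82.5 reads in library 2. Within library 2, peaks on chromosomes 1 to 19, X and Y had a median pileup of 32 and a median fold of 9.10, and peaks on unplaced sequence had 95 and 3.67. The genome-wide background was 2.71 extended reads in library 1 and 1.05 in library 2. In library 1, 386859 peaks (66.2%) were called against that background and 74 peaks (0.0127%) lay where the local background was over 10 times as high. In library 2 these numbers were 62 (17.8%) and 204 (58.6%). With the caller's preset genome size, the backgrounds correspond to 42.6 M reads in library 1 and 38.3 M reads in library 2. The numbering of the peaks ran to 587530 in library 1 and to 570 in library 2, so 2806 numbers (0.478%) and 222 numbers (38.9%) were missing from the lists.

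The strongest peaks of library 1 inside genes lay in F13a1, Shisa6 and Epha3. F13a1 encodes a subunit of coagulation factor XIII, and its peak at chromosome 13, 36978295 to 36978985, had a fold enrichment of 14.2 and a pileup of 57 reads (95% interval 43.2 to 73.9). The peak in Shisa6, which encodes a partner of AMPA receptors, lay at chromosome 11, 66420882 to 66421325, with a fold of 12.4 and a pileup of 74 (58.1 to 92.9). The peak in the ephrin receptor gene Epha3, at chromosome 16, 63833434 to 63833836, had a fold of 12.4 and a pileup of 51 (38.0 to 67.1). They were followed by Il15ra (11.3), Sdccag8 (10.8), Dpp10 (10.2), Clpx (10.01), Pcsk2 (9.96), Cd163l1 (9.87) and Eea1 (9.69), the values being folds. All 10 summits lay within the annotated gene, and exon or intron positions were not used here. The highest peak of the list, at chromosome 17, 25451757 to 25451964, had a fold of 16.1 and no protein-coding gene within 1 kb.

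In library 2 the strongest peak lay in Dpp9, which encodes a dipeptidyl peptidase. It spanned chromosome 17, 56200008 to 56200089, with a fold of 35.2 and a pileup of 71 (55.5 to 89.6). The peak in Myo7a, an unconventional myosin gene of inner ear and retina, lay at chromosome 7, 98060025 to 98060094, with a fold of 20.05 and a pileup of 40 (28.6 to 54.5). Further folds were 16.1 in Pcnx2, 12.7 in Ica1, 11.7 in Mamdc2 and Plxdc2, 11.6 in Hs6st3 and Ano2, and 11.2 in Trhde. None of these genes was among the 10 named for library 1. In all, 31 protein-coding genes had a library 2 peak in the body or within 1 kb.

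Few positions were shared between the lists. Of the 348 peaks of library 2, 17 (4.89%, 2.87 to 7.71) touched a library 1 peak. Random placement on the same sequences gave a mean of 57.2 peaks (16.4%, range 38 to 78), and the one-sided p for more overlap than random was 1. On chromosomes 1 to 19, X and Y, 9 of 127 peaks (7.09%, 3.29 to 13.0) overlapped, against 7.73% for random placement (permutation p = 0.658). The 62 library 2 peaks called at the genome-wide background, whose median fold was 10.3, included 3 overlapping peaks (4.84%, 1.01 to 13.5).

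Some library 2 peaks on chromosomes lay close together, and clustering was not tested. A stretch of chromosome 14, 19415737 to 19419663, held 16 peaks with folds of 1.68 to 6.50, where the median background was 32.5 times that of the genome. Chromosome 17, 13586467 to 13591557, held 6 peaks, and chromosome 9, 124256365 to 124257832, held 5. A further 4 peaks lay on the Y chromosome between 90763641 and 90775438.

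The X and Y chromosomes carried far fewer library 1 peaks per Mb than any autosome. Autosomes held 240.0 peaks per Mb together, from 169 on chromosome 3 to 336 on chromosome 11, with 297 on chromosome 17. The X chromosome held 5149 peaks, or 30.7 per Mb (29.8 to 31.5), which was 0.128 of the autosomal density. The Y chromosome held 2251 peaks, or 24.8 per Mb (23.8 to 25.9), a ratio of 0.103. Over the 19 autosomes, peak density followed the density of protein-coding genes (Pearson r = 0.81, p = 1e-05, the smallest the permutations allow; Spearman rho = 0.83, p = 3e-05). Without chromosomes 7 and 11, which were farthest from the median gene density, r was 0.78 (permutation p = 0.00024) and rho was 0.79 (p = 0.00042). In library 2, the X chromosome held 3 peaks and the Y chromosome 6.

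**Figure D1:**
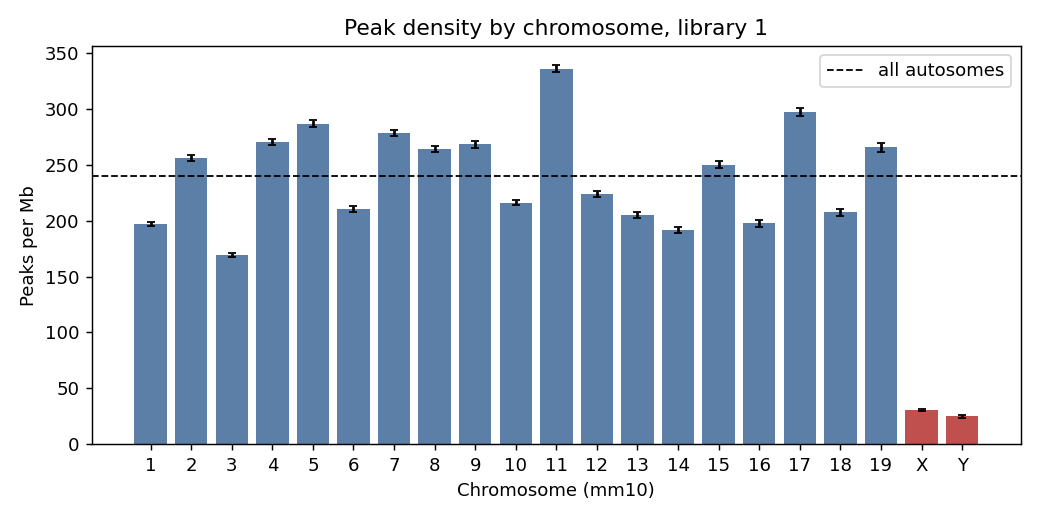
Library 1 peaks per Mb (vertical axis) on each chromosome of mm10 (horizontal axis), as bars with 95% exact Poisson intervals; autosomes are blue, sex chromosomes red, and the dashed line is the density over all autosomes. The X bar stands at 30.7 and the Y bar at 24.8, below the lowest autosome, chromosome 3, at 169.

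Library 1 peaks were more frequent at the ends of protein-coding genes and inside them than random placement gave, and less frequent between genes. A peak lay within 1 kb of either end of 17148 of 21887 genes (78.3%, 77.8 to 78.9), against 62.4% for random placement (permutation p = 0.0198). Of 584075 summits, 6.30% lay within 1 kb of such an end, 1.97 times the random share, and 49.7% lay inside a gene, 1.26 times the random share. Between genes lay 35.7%, 0.726 times the random share, and other annotated genes held 8.21%, equal to the random 8.21%. Each of the first 3 differences had a permutation p of 0.0198. Random placement spread peaks evenly along each chromosome, so part of these ratios can reflect wider regions around genes rather than the ends themselves. The direction turned in a wider window. Within 5 kb of an end, 90.3% of genes had a peak, against 94.3% for random placement.

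Around the ends of 9575 autosomal genes longer than 20 kb, summit density was highest 250 to 500 bp inside the gene, at 726 per Mb (702 to 751). The lowest density, 310 per Mb (295 to 327), lay outside the gene at a distance of 1500 to 1750 bp. Far from the end, at 8 to 10 kb, densities were 371 per Mb outside and 391 per Mb inside. Both were above the 240.0 per Mb of all autosomes.

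**Figure D2:**
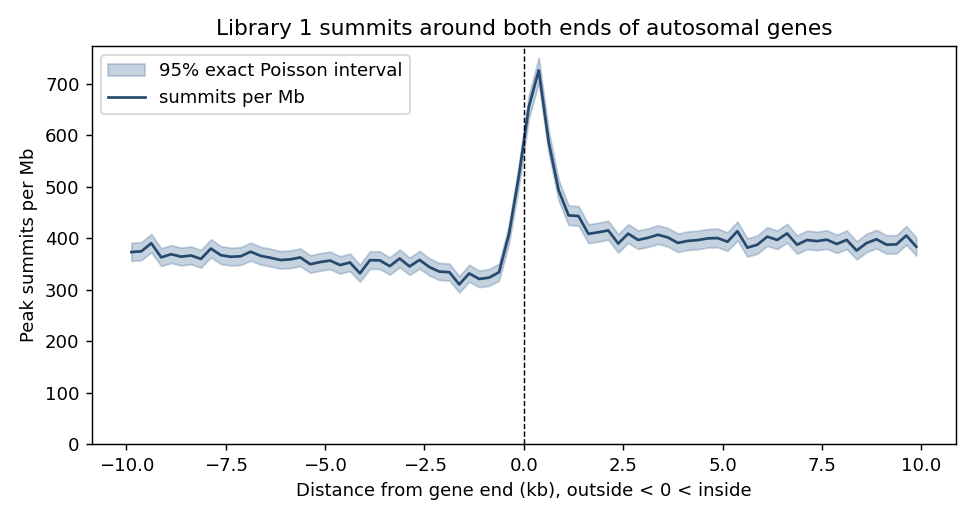
Library 1 summits per Mb (vertical axis) in bins of 250 bp against the distance from a gene end in kb (horizontal axis, negative outside the gene), pooled over both ends of 9575 autosomal genes longer than 20 kb; the line is the density and the shading its 95% exact Poisson interval. Density peaks at 726 just inside the end and dips to 310 outside it.

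No protein-coding gene had a library 2 peak within 1 kb of an end (0 of 21887, exact upper limit 0.0169%), where random placement of its 127 peaks gave a mean of 4 genes (p = 0.0792). Of the 127 summits, 33 (26.0%, 18.6 to 34.5) lay inside protein-coding genes, against 38.6% at random (permutation p = 0.0198). Between genes lay 85 (66.9%, 58.0 to 75.02), against 50.7% (permutation p = 0.0198). Neighbouring peaks are not independent, and both calls were lost with 1 peak per run of peaks within 10 kb. Of the 94 peaks left, 33.0% (23.6 to 43.4) lay inside genes (permutation p = 0.297) and 58.5% (47.9 to 68.6) between genes (permutation p = 0.178).

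Among the genes that guide eye formation, 41 of 48 eye and lens regulators (85.4%, 72.2 to 93.9) had a library 1 peak at an end, and the difference from other genes (78.3%) did not pass the test (Fisher's exact test, adjusted p = 0.383). The direction turned among stronger peaks, to 39.6% against 48.1% with −log10 q of at least 5, and the test was again not passed (Fisher's exact test, adjusted p = 0.386). The highest folds in the group were 5.92 at Bmp4, a ligand needed for lens induction, and 5.48 at Mitf, a regulator of the retinal pigment epithelium. Rax and Pitx3 each had a best fold of 5.12 at an end, Sox2 4.59, Six3 and Foxe3 4.31, and Pax6 4.04. The Pax6 peak, at chromosome 2, 105698610 to 105698925, rested on a pileup of 14 reads (7.65 to 23.5), and 9 further peaks lay in the gene body. Otx2 had no peak at an end and 4 in its body. None of these 7 regulators had a library 2 peak.

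All 30 crystallin and lens fibre genes, which encode the refractive proteins and the cytoskeleton of lens cells, had a peak at an end (100%, 88.4 to 100; Fisher's exact test, adjusted p = 0.00405). Cryga and Crygf had folds of 6.19, a value shared by Tdrd7, named here after its value was seen. The call held with genes of the same length (exact test, adjusted p = 0.00471) and on autosomes (Fisher's exact test, adjusted p = 0.0125). It was lost when the list was rotated along the gene order (permutation test, adjusted p = 0.133). It was also lost at the lower gene end alone (Fisher's exact test, adjusted p = 0.109). The call held with −log10 q of at least 5, at 83.3% against 48.0% (Fisher's exact test, adjusted p = 0.00023). The shares were 36.7% and 15.5% among the 10% of peaks with the highest fold (Fisher's exact test, adjusted p = 0.0124). Photoreceptor genes had a peak in 20 of 30 cases (66.7%, 47.2 to 82.7; Fisher's exact test, adjusted p = 0.21), with folds of 6.73 at Rcvrn and 6.19 at Pde6a.

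Hox genes, which set position along the body axis, had a peak at an end in 38 of 39 cases (97.4%, 86.5 to 99.9; Fisher's exact test, adjusted p = 0.00405). Hoxd4 had a fold of 5.92 and Hoxc4 of 5.39. This call was lost under rotation (permutation test, adjusted p = 0.372), and the direction turned among peaks with −log10 q of at least 5, where 38.5% of Hox genes and 48.1% of other genes had a peak. Signalling genes were called at 33 of 35 (94.3%; Fisher's exact test, adjusted p = 0.041), led by the retinoic acid pathway genes Aldh1a2 and Rara with folds of 6.46. That call was lost with genes of the same length (exact test, adjusted p = 0.167), on autosomes (Fisher's exact test, adjusted p = 0.142) and under rotation (adjusted p = 0.189). Its direction turned at the stricter threshold (45.7% against 48.0%). Neural patterning regulators (35 of 40, 87.5%; Nkx2-1 and Nkx2-2, folds of 6.19) and neural crest regulators (27 of 30, 90%; Alx4 and Dlx3, 5.66 and 5.65) did not pass Fisher's exact test (adjusted p = 0.258 for each).

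Among genes of other cell types, all 20 endothelial genes had a peak at an end (100%, 83.2 to 100; Fisher's exact test, adjusted p = 0.0262), with folds of 6.73 at Kdr and Robo4. The call was lost with genes of the same length (exact test, adjusted p = 0.0548), on autosomes (adjusted p = 0.0779) and under rotation (adjusted p = 0.126). It held with −log10 q of at least 5, at 80% against 48.0% (Fisher's exact test, adjusted p = 0.014). It was lost among the 10% of peaks with the highest fold, at 35% against 15.5% (Fisher's exact test, adjusted p = 0.055). Keratin-associated protein genes, which encode hair shaft proteins, had a peak in 49 of 52 cases (94.2%; Fisher's exact test, adjusted p = 0.00856), with folds of 8.62 at Krtap1-4 and 8.08 at Krtap9-3. Genes of their length had a peak in 43.1% (exact test, adjusted p = 1.92e-14), while rotation gave an adjusted p of 0.383. Random placement gave 56.5% for this list, above the share in genes of the same length. The median length was 0.82 kb here, near the 0.95 and 0.96 kb of olfactory and vomeronasal receptor genes, which had few peaks. Genes of the same length can include many of these receptors, so the contrast by length may be too large. Against all other genes, the keratin-associated call held with −log10 q of at least 5, at 84.6% against 48.0% (Fisher's exact test, adjusted p = 2.3e-07). It also held among the 10% of peaks with the highest fold, at 59.6% against 15.4% (Fisher's exact test, adjusted p = 2.6e-12). Within 5 kb of an end, none of the 5 lists called higher (crystallin, Hox, signalling, endothelial and keratin-associated protein genes) passed Fisher's exact test (adjusted p from 0.125 to 0.389). At the higher gene end alone, the calls for Hox, signalling and endothelial genes were lost (Fisher's exact test, adjusted p from 0.208 to 0.886). Hepatocyte genes (25 of 30, 83.3%; Tat 7.002, Itih1 6.73), germline genes (26 of 30, 86.7%; Mael 6.73, Prm1 6.46) and blood cell genes (18 of 24, 75%; Epb42 6.20, Nfe2 6.06) did not pass Fisher's exact test. Nor did genes of chromatin and H3 chaperones (23 of 30, 76.7%; Dnmt3a 5.92, Cabin1 5.66), and the adjusted p-values of these 4 lists ranged from 0.455 to 0.825. Germline genes passed it among stronger peaks: with −log10 q of at least 5, 70% had a peak at an end against 48.0% of other genes (Fisher's exact test, adjusted p = 0.0369). Among the 10% of peaks with the highest fold, their share was 33.3% against 15.5% (Fisher's exact test, adjusted p = 0.0448).

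Histone, ribosomal protein and chemosensory receptor genes had a peak less often than other genes, and these 4 lists passed the tests by gene length, on autosomes and by rotation. No single test took both gene length and neighbouring genes into account. Rotation gave a mean of 81.6% for histone and 81.8% for olfactory receptor genes, where genes of the same length gave 44.3% and 46.7%. The autosome and rotation tests can therefore partly reflect short genes. The test by length treats neighbouring genes as independent. None of these tests bears on how uniquely reads map to a gene, which was not examined for these lists. Replication-dependent histone genes had a peak at an end in 10 of 63 cases (15.9%, 7.88 to 27.3; Fisher's exact test, adjusted p = 3.27e-25), against 44.3% for genes of the same length (adjusted p = 5.54e-06) and with a rotation adjusted p of 0.00425. The highest fold, 5.66, belonged to a peak shared by the neighbours H2ac1 and H2bc1. Ribosomal protein genes had a peak in 49 of 81 cases (60.5%, 49.0 to 71.2; Fisher's exact test, adjusted p = 0.00144), against 73.9% at the same length, and Rpl3l and Rpl32l led with 6.46 and 5.66. Within 5 kb their share was 96.3%, above that of other genes (90.3%), and the test was not passed. Olfactory receptor genes had a peak in 311 of 1106 cases (28.1%, 25.5 to 30.9; Fisher's exact test, adjusted p = 1.7e-296), with folds of 7.54 at Olfr329 and Olfr66. Vomeronasal receptor genes had a peak in 50 of 353 (14.2%, 10.7 to 18.2; adjusted p = 3.57e-148 by the same exact test), with 6.20 at Vmn2r79 and 6.19 at Vmn1r88.

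**Figure D3:**
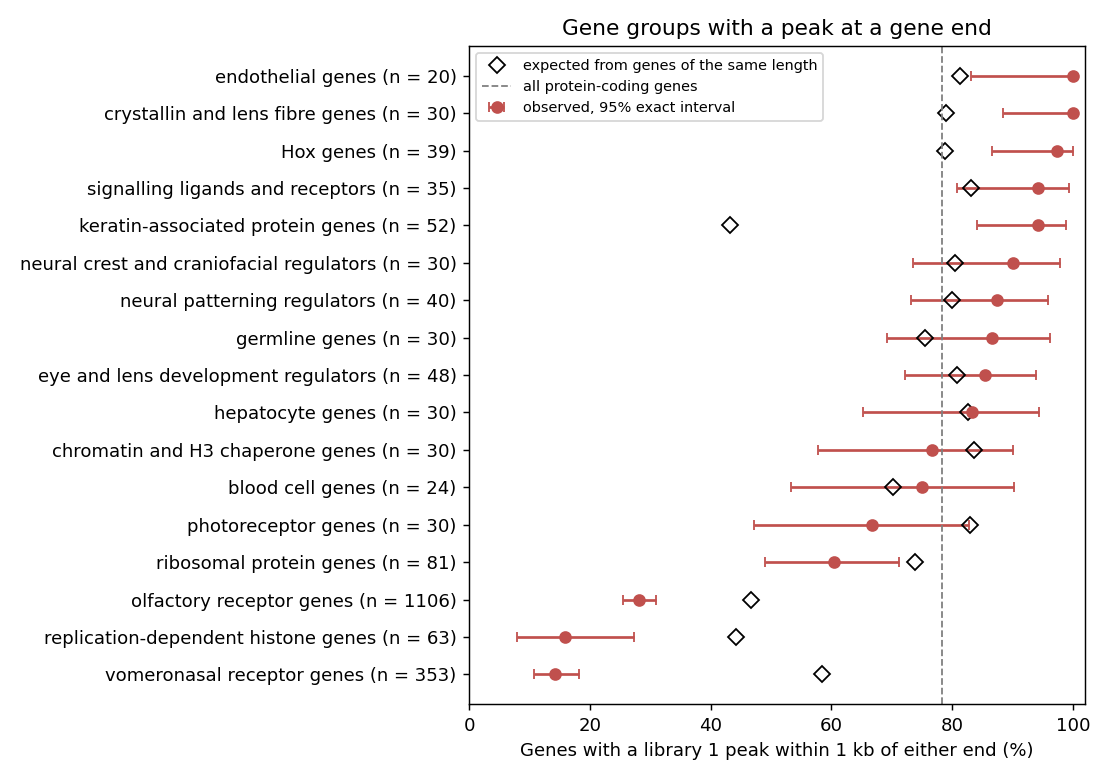
Share of genes with a library 1 peak within 1 kb of either end (horizontal axis, %) for the 17 gene lists (vertical axis, with the number of genes); filled circles are observed shares with 95% exact intervals, open diamonds the share expected from genes of the same length, and the dashed line the share over all protein-coding genes. Histone genes lie at 15.9% and vomeronasal receptor genes at 14.2%, while crystallin and endothelial genes lie at 100%.

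None of the 8 genes that encode histone H3.2 had a peak in either library. H3c2, H3c3, H3c4, H3c6 and H3c7 lie on chromosome 13 between 23544052 and 23752840, and H3c13, H3c14 and H3c15 lie on chromosome 3 between 96238479 and 96269155. For each, no peak was found within 1 kb of an end or in the gene body. These genes are near-identical copies, so reads from them can map to several places. In library 2 no member of any of the 17 lists had a peak at an end, as no protein-coding gene did, so the lists could not be tested there.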

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

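The tests by gene length, on autosomes only, by rotation, on a single gene end, with 1 library 2 peak per run of neighbouring peaks, and the overlap on chromosomes 1 to 19, X and Y, were chosen after the results were seen. Of the alternatives for results that answer a comparison, 35 kept their direction and call or, for plain counts, stayed close to the reported count. Counts of 7 or 8 called lists in place of 9 are among these, and in them single lists lost their call. Among the 35 was every alternative for the overlap of the lists, whose share ranged from 2.01% to 7.09%. That test looked only for more overlap than random, so a kept call says nothing about the size of a shortfall. On the same sequences, the 17 overlapping peaks lay below the random range (38 to 78). With placement anywhere in the genome they lay within it (12 to 43). On chromosomes 1 to 19, X and Y, the 9 overlapping peaks also lay within the random range (3 to 20). With −log10 q of at least 5, library 1 kept 239499 peaks, and the X and Y ratios were 0.102 and 0.0734. With a fold of at least 5, libraries 1 and 2 kept 92444 and 142 peaks. On chromosomes 1 to 19, X and Y, library 2 kept 127. These falls follow from the filters themselves, except for the 2 ratios, where the cause was not tested.

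A window of 5 kb turned the direction for library 1 (90.3% of genes against 94.3% at random), called library 2 below random (0.0411%, permutation p = 0.0396), and called 3 gene lists in place of 9. It turned ribosomal protein (96.3%), photoreceptor (93.3%), blood cell (95.8%) and chromatin genes (93.3%) above other genes. Rotation called 4 lists. At −log10 q of at least 5, eye and lens regulators (39.6%), Hox (38.5%) and signalling genes (45.7%) turned below other genes, and photoreceptor genes (50%) above. Among the 10% of peaks with the highest fold, eye and lens regulators (8.33%), neural patterning regulators (12.5%), Hox (7.69%) and signalling genes (11.4%) turned below, and chromatin genes (16.7%) above. Chromatin genes also turned above on autosomes and under rotation (82.1% in each). Blood cell genes turned above with genes of the same length (75%) and at either single end (62.5% in each), and eye and lens regulators turned below at the lower end (58.3%). Summits in other annotated genes turned above random in library 1 with any base (8.39%) or −log10 q of at least 5 (8.23%), and in library 2 with 1 peak per run (8.51%). None of these turned values passed its test, apart from the share of all genes in library 1, and the cause was not tested. Counting any base of a peak, library 2 had 0% near gene ends, now past the threshold (permutation p = 0.0396). With 1 peak per run within 10 kb, library 2 shares inside genes (33.0%) and between genes (58.5%) lost their calls, with fewer and more independent peaks. Of the single gene lists and similar results, 95 alternatives kept direction and call, 19 lost the call, 3 gained it and 19 turned.

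GC-matched gene lists, and GC content and repeats of the peaks, were not run, since no genome sequence was used. Leaving out a library was not applied, because each library is reported on its own and the overlap needs both. No paired analysis was possible because there is a single group. With 348 peaks, library 2 gives wide intervals for any share.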

Other observations

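The gene family survey, the sex chromosome regions and the tests of sequencing depth, control library and extension length were chosen after the results they bear on were seen. Grouping autosomal genes by the leading letters of their symbols gave 116 families with at least 20 members. After matching on gene length, 17 had a library 1 peak at an end less often and 7 more often than other genes (exact conditional test, Benjamini-Hochberg over families). Of these, 7 and 3 also passed the rotation test. The 7 were the stems H, LOC, Olfr, Pramel, Prl, Tas and Vmn. Olfr and Vmn repeat the receptor lists above, H takes in the histone genes, and LOC marks loci without a gene name. A shared stem is therefore not always a gene family, and these counts are not all new results. Prolactin family genes (Prl), which act in placenta and pituitary, had a peak in 0 of 25 cases, against 85.3% at the same length (exact adjusted p = 6.14e-20). Pramel genes had one in 11 of 45 (24.4%, exact adjusted p = 5.07e-17), and the taste receptor family (Tas) in 8 of 38 (21.1%, adjusted p = 0.003). Major urinary protein genes (Mup), made in liver, had one in 1 of 24 (4.17%, exact adjusted p = 4.31e-15), but their rotation adjusted p was 0.108. How uniquely reads map within these families was not examined, so a low share cannot be read as a property of the genes alone.

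At the other extreme, all 53 keratin genes (Krt) and all 23 claudin genes (Cldn), which encode tight junction proteins, had a peak at an end. Genes of their lengths had one in 84.4% and 69.3% of cases (exact adjusted p = 0.00165 and 0.0012), and both calls were lost under rotation (0.317 and 0.189). Genes of the same length can include chemosensory receptors, which had few peaks, so contrasts by length may be too large here as well. The ring finger family (Rnf, 77 of 80, 96.3%; exact adjusted p = 0.00346) passed both tests. Low ribosomal protein and histone genes raised the hypothesis that genes active in most cells hold fewer peaks. The test pooled 391 genes of mitochondrial ribosome, respiratory chain, proteasome, translation factor, polymerase, splicing and ATPase families. They had a peak in 347 cases (88.7%, 85.2 to 91.7), more than the 80.3% of genes of the same length (exact p = 6.0e-06). Receptor genes may lower that expected share, so the difference may be too large. Autosomal genes other than olfactory receptors had a peak in 84.9% of cases, without matching on length. The pooled share was below neither value, which argues against that hypothesis for the pooled families only. The genes were picked by the leading letters of their symbols, and expression was not measured.

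Library 1 and library 2 differed in number and position of peaks despite identical labels. Lower depth or another control library cannot account for this, since the ratio of recovered depth, library 2 over library 1, was 0.899, and the ratio of control depths was 1. The shorter extension of library 2 remains open: 4.84% (1.01 to 13.5) of its background-level peaks overlapped library 1, but these are part of the low overlap itself, and the effect of extension on the number of peaks was not tested. A difference in the immunoprecipitated material is open too and was not tested. Peak numbers ran to 570 in library 2 and to 587530 in library 1. This argues against removal of numbered peaks as the cause of the difference in number. For position, such filtering stays open and was not tested, as 38.9% of library 2 peak numbers were missing against 0.478%. A difference in material would include a library made as a control, which the labels neither state nor exclude, and with no group to compare, no biological explanation was tested.

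The X chromosome had 0.128 of the autosomal peak density in library 1. Few genes cannot account for it, since 223 autosomal bins of 5 Mb with no more genes per Mb than X had a median density 4.18 times that of X bins, and removal of peaks after calling left only 33 missing numbers (0.641% of X peaks). A single X copy in male embryos may contribute. Random thinning of autosomal background-level pileups to a single copy left 45.0% of peaks at or above 8 reads, the smallest pileup called there. X had 12.8% of the autosomal density, so a single copy alone did not reach the observed fall in this simulation. The thinning treated all material as male, and female material would leave more peaks. The size of the contribution cannot be told, because the labels give no sex and the thinning is simulated. Beyond Mid1, near the X end that pairs with Y, density was 68.4 per Mb (52.2 to 88.1). That was above the 30.7 of X as a whole and below the 240.0 of autosomes. From Zfy1 to Sry on Y it was 32.0 (24.5 to 41.0), with 62 peaks. Peaks placed there point to male material in library 1, but they do not give its share. How uniquely reads map in that stretch was not examined. No biological explanation was tested.

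Few histone genes had a library 1 peak, 10 where genes of the same length gave 27.9. Short genes, which give short windows, cannot account for this, since the deficit remained after matching on length (exact p = 1.3e-06). Reads shared between near-identical copies may remove signal, but density relative to the chromosome mean was 0.512 (0.245 to 0.941) in the gene bodies, 0.116 (0.0141 to 0.421) within 1 kb outside and 0.457 (0.250 to 0.766) at 1 to 5 kb outside. The low flanks argue against it as the whole cause, and it stays open because the similarity of the flanks was not examined and the interval at 1 to 5 kb is wide. A region low in peaks cannot be told apart from this either: other genes within 100 kb had a peak in 69.2% of 26 cases (48.2 to 85.7), against 78.5% elsewhere, and no biological explanation was tested.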
